A study of Homo sapiens with 8 samples.

How the data were processed

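RNA sequencing of NB4 cells was available as 8 libraries, 2 for each of 4 groups: empty vector, full-length PML/RARα, F158E and ΔIDR, all after knock-down of the endogenous fusion and 72 h of infection. Per the labels, total RNA was depleted of ribosomal RNA before library preparation with the NEBNext Ultra kit, which does not mark the strand. The deposited values are raw counts per gene that the authors made for each library, with no normalization, against the human genome builds hg38 and GRCh38 per the submitters' processing notes. The aligner, the counting program, their versions and the annotation release were not given in the sources used here. Each file held 60483 gene identifiers and 5 further lines for reads that were not assigned to a gene.

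Of the reads recorded in each file, 87.9% to 88.7% were assigned to genes, which gave 16779364 to 21965389 counts in a library. The gene identifiers were matched to symbols in a reference of gene names, which held 56321 of them. GENCODE release 29 gave types and positions, and symbols for identifiers that this reference lacked. A count near 0 does not show that a gene was off: XBP1 had 0 counts in each library, and 149 of the 190 list members that were not tested had 5 counts or fewer in every library. Correlations of replicate deviations between groups ran from -0.0163 to 0.0206, so no replicate effect shared across groups was visible. This does not show that replicates were handled apart. The main fit used no replicate block. The edgeR fit gave a square root of the common dispersion of 0.0486.

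Differential expression was tested with edgeR 4.0.16 in R 4.3.3, by quasi-likelihood fits over all 8 libraries with TMM factors (0.989 to 1.01) and the filterByExpr rule, which left 13982 genes, of which 11608 were protein coding. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within each of 6 comparisons, and log2 fold changes and SE came from the same fit. Levels are CPM from edgeR with TMM scaling. In this design 2 libraries per group set the residual spread, and moderation across genes supplied most of the degrees of freedom.

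The groups, the comparisons, 27 gene lists, the rule for named genes and most alternative settings were written down before the data were examined. The lists covered the fusion partners, granulocyte, monocyte and other blood lineages, myeloid transcription factors, retinoic acid, interferon and NF-kB responses, antigen presentation, cell cycle, histones, ribosomes, mitochondrially encoded genes, p53, stress responses, cholesterol, hypoxia, coagulation, PML bodies, nuclear receptor coregulators, and markers of lymphoid, erythroid, epithelial and mast cells. Lists with at least 3 tested members were tested with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over lists within a comparison. Camera was repeated with the correlation estimated for each list, and fry was run as a second list test. A call lost in the repeated run was not shown to be lost through correlation among members, since some estimates lay below the preset value.

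Named genes were PML and RARA, the 6 largest rises and 6 largest falls among called protein-coding genes with a mean of at least 3 log2 CPM and replicates that did not overlap, and a fixed panel of regulators and markers. To these were added, for each list that camera called or in which at least 3 members passed, the 3 members with the smallest adjusted p in the majority direction and 1 in the other direction. For the comparisons that did not involve full-length PML/RARα, the rule took the 3 largest rises and falls and 2 members of each such list. Genes that the text names outside this rule are marked where they appear.

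The position of a mutant library was its least-squares place along the difference between empty vector and full-length means of log2 CPM, over genes called between these groups, with a prior count of 2. Overlaps of calls were set beside the number expected under independence and beside 20 simulations in which groups did not change but shared the same control libraries.

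The fits were tested on simulated data with known changes. At a simulated log2 change of 0.5, edgeR recovered 44.8% to 67.2% of changed genes. At 1 it recovered 68.7% to 82.1%, and at 2 it recovered 72.7% to 87.9%. Of unchanged genes, 0.0145% to 0.0654% were called. Each simulated comparison held 66 or 67 changed genes at each of these sizes and 13752 unchanged ones. The real comparisons called 1208 to 6950 genes, and more calls let more unchanged genes pass the same adjusted p limit. The simulated error rate is therefore not that of the real calls. Camera called 6 of 6 moved lists and 0 of 6 still lists. These lists were random genes with independent counts, so they do not show how camera behaves where list members vary together. A group simulated midway between empty vector and full-length PML/RARα was placed at 0.515, and a group simulated at empty vector at 0.0422. The pass mark set for recovery was lowered after a first run missed it.

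Alternatives were DESeq2 size factors, library totals alone, no count filter, a mean of at least 1 CPM, DESeq2 1.42.0, limma-voom, the 4 libraries of a comparison alone, protein-coding genes off the mitochondrial chromosome, a fold change of at least 2, a replicate block, a loess correction for GC content with and without the block, and leaving out each library in turn. A test against a fold change of 1.5, counts thinned to 1 part in 3, the mature granulocyte list without NCF1, and overlaps with 1 full-length or 1 empty vector library in each comparison were added after the data were seen. No values for the knock-down, for fusion protein or for the endogenous fusion transcript could be derived from counts per gene.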

Results

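RNA was sequenced from 8 libraries of NB4 cells, an established acute promyelocytic leukemia line that carries the PML/RARα fusion of a nuclear body protein with a retinoic acid receptor. The endogenous fusion had been knocked down, and for 72 h the cells carried either an empty vector, HA-tagged full-length PML/RARα, or the mutants F158E and ΔIDR, which the labels call incompetent for phase separation. The design made 4 groups of 2 libraries. Gene counts summed to 18613826 and 19037914 in the empty vector libraries, 17372297 and 16979684 with full-length PML/RARα, 21930353 and 21918365 with F158E, and 16779364 and 21965389 with ΔIDR. Fold changes below are log2 values ± SE from edgeR, with n = 2 libraries in each group, and levels are CPM, counts scaled to a common library total, ± SD over the same 2 libraries. Nothing in the labels says that the 2 libraries of a group came from separate cultures. The edgeR p-values thus measure only the spread between these libraries, which may be technical. Camera p-values at the preset correlation compare a list with the other genes, and are not a measure of the spread between libraries.

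The genes that make up the fusion, PML and RARA, were counted in each group. RARA (ENSG00000131759.16, chromosome 17, positions 40309192 to 40357643 of GRCh38), a retinoic acid receptor gene, was at 23.1 ± 1.41 CPM with empty vector, 77.0 ± 1.88 with full-length PML/RARα, 32.3 ± 0.181 with F158E and 1358 ± 9.67 with ΔIDR. PML (ENSG00000140464.18, chromosome 15, positions 73994673 to 74047812), the nuclear body scaffold gene, was at 51.9 ± 1.28, 124 ± 4.33, 65.9 ± 0.219 and 442 ± 3.42 CPM in the same order. Above empty vector, F158E cells held 0.171 of the RARA CPM and 0.194 of the PML CPM that full-length cells held, and ΔIDR cells held 24.8 and 5.40 times as much. The ratio of PML to RARA CPM above empty vector was 1.34 with full-length PML/RARα, 1.52 with F158E and 0.293 with ΔIDR. A count per gene sums the normal alleles, the endogenous fusion and the transgene, so the excess over empty vector was not shown to be transgene RNA alone. The labels do not say which parts of PML the ΔIDR construct holds. No library lacked the knock-down, so neither the knock-down nor fusion protein was measured.

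**Figure D1:**
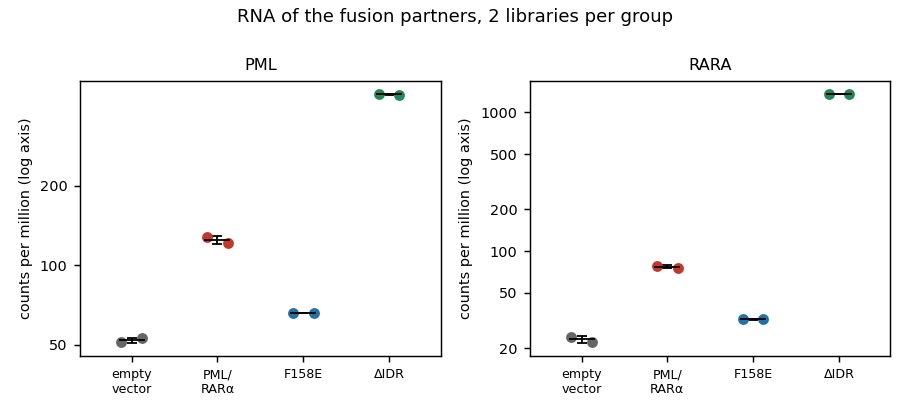
PML and RARA CPM on a log axis in the 4 groups; points are libraries, bars are the mean of 2 and error bars the SD. ΔIDR libraries were highest for both genes, and F158E libraries lay between empty vector and full-length PML/RARα.

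The comparison of full-length PML/RARα with empty vector asked what the fusion adds to depleted cells. CXCL8 (ENSG00000169429.9), a neutrophil-attracting chemokine, went from 488 ± 2.58 to 33.8 ± 1.62 CPM, a 14.4-fold fall. The cytokine gene IL1B fell 15.8-fold, from 38.3 ± 2.40 to 2.43 ± 0.858 CPM, and the monocyte-attracting chemokine gene CCL2 fell 10.8-fold. HSPA5, the main chaperone of the endoplasmic reticulum, fell from 2496 ± 8.71 to 979 ± 18.7 CPM, and INSIG1, a sterol-responsive regulator, fell from 434 ± 4.20 to 134 ± 4.02 CPM. CEBPE, a transcription factor of late granulocyte development, fell from 65.7 ± 1.38 to 26.8 ± 1.5 CPM. RRP1B, a nucleolar gene of ribosome assembly, rose from 131 ± 4.79 to 265 ± 8.16 CPM. In every one of these genes both libraries of one group lay outside the range of the other group.

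Of the lists of genes fixed in advance, cholesterol biosynthesis genes fell in 22 of 26 tested members and rose in 2 (23 and 2 adjusted over the list alone), with 2 not passing. Their median log2 change was -0.72, and camera gave an adjusted p of 7.66e-17. HMGCS1, an early enzyme of sterol synthesis, fell by 1.53 ± 0.04 on the log2 scale, while EBP, a later enzyme, rose by 0.66 ± 0.07. Unfolded protein and integrated stress response genes fell in 24 of 30 members and rose in 3 (24 and 3 adjusted over the list alone), with a median of -0.72 and a camera adjusted p of 3.29e-16. Among them the chaperone genes HSP90B1 and CALR fell by 1.05 ± 0.02 and 1.14 ± 0.02. NF-kB and inflammatory response genes fell in 26 of 35 members and rose in 3 (27 and 3 adjusted over the list alone), with a median of -1.68 and a camera adjusted p of 2.37e-12. TNFAIP3, a brake on NF-kB signalling, fell by 3.13 ± 0.08 and the adhesion molecule gene ICAM1 by 3.14 ± 0.06, and TNIP1, another inhibitor, rose by 0.41 ± 0.08.

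Ribosome biogenesis and MYC target genes rose in 38 of 51 members and fell in 5 (38 and 5 adjusted over the list alone), with a median of 0.34 and a camera adjusted p of 5.23e-12. The nucleolar helicase gene DDX21 rose by 0.41 ± 0.02, the purine synthesis gene PAICS by 0.42 ± 0.03 and MYC itself by 0.34 ± 0.03, and the transferrin receptor gene TFRC fell by 0.70 ± 0.02. Cytosolic ribosomal protein genes rose in 42 of 70 members and fell in 4 (43 and 5 adjusted over the list alone), by a median of 0.09, with a camera adjusted p of 1.00e-08. The 13 mitochondrially encoded genes split into 3 that rose and 10 that fell (3 and 10 adjusted over the list alone), with a median of -0.19 and a camera adjusted p of 1.00e-08. The mitochondrial share of counts was 3.33% in both full-length libraries and 3.71% and 3.72% in the empty vector libraries.

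Genes of granulocyte development mostly fell with full-length PML/RARα. Primary granule and promyelocyte genes fell in 18 of 23 members and rose in 2 (18 and 3 adjusted over the list alone), with a median of -0.40 and a camera adjusted p of 1.04e-09. The granule proteoglycan gene SRGN fell by 0.98 ± 0.02, the granule protein gene AZU1 by 1.40 ± 0.08 and the myeloperoxidase gene MPO by 0.14 ± 0.02, and CST7, a protease inhibitor gene, rose by 1.46 ± 0.25. Mature granulocyte genes fell in 19 of 34 members and rose in 4 (19 and 4 adjusted over the list alone), with a median of -0.84 and a camera adjusted p of 6.04e-05. The gelatinase gene MMP9 fell by 2.45 ± 0.05 and the oxidase subunit genes NCF1 and CYBB by 3.15 ± 0.10 and 0.64 ± 0.03. The G-CSF receptor gene CSF3R and the panel gene ITGAM, an integrin subunit, rose by 1.09 ± 0.14 and 0.33 ± 0.12. NCF1 has near-identical copies elsewhere in the genome, so its count may include or lose reads of those copies. Retinoic acid response genes fell in 16 of 28 members and rose in 4 (17 and 4 adjusted over the list alone), with a median of -0.55 and a camera adjusted p of 1.53e-05, and included CD38, an ectoenzyme induced by retinoic acid, which fell by 1.96 ± 0.06.

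Interferon-stimulated genes fell in 26 of 43 members and rose in 6 (26 and 7 adjusted over the list alone), with a median of -0.49 and a camera adjusted p of 1.59e-04. IFIT2 and IFIT3, antiviral effectors, fell by 2.25 ± 0.13 and 2.30 ± 0.12, and MX2, an antiviral GTPase, rose by 0.39 ± 0.05. Myeloid transcription factors fell in 24 of 42 members and rose in 7 (24 and 8 adjusted over the list alone), with a median of -0.33 and a camera adjusted p of 0.00236. CEBPA, SPI1 and GFI1, regulators of granulocyte and monocyte fate, fell by 0.55 ± 0.06, 0.44 ± 0.05 and 0.32 ± 0.05. Basophil, eosinophil and mast cell markers fell in 7 of 11 members and rose in 0 (7 and 0 adjusted over the list alone), with a median of -1.02 and a camera adjusted p of 0.00152, and this call was lost at an adjusted p = 0.0841 with an estimated correlation. The eosinophil granule gene PRG2 fell by 1.14 ± 0.04 and GATA2, a mast cell and progenitor factor, by 1.22 ± 0.05. The hypoxia, monocyte, promyelocytic leukemia and coagulation lists had camera adjusted p values of 0.00713, 0.00960, 0.0210 and 0.0275, each lost with an estimated correlation, at adjusted p = 0.0965, 0.0965, 0.0965 and 0.155. Their members rose, fell and did not pass in 12, 5 and 11 cases for hypoxia, in 0, 8 and 10 for monocyte genes, in 4, 9 and 6 for promyelocytic leukemia genes, and in 2, 5 and 7 for coagulation genes. Adjusted over the list alone, 13 hypoxia genes rose and 5 fell, and the other 3 counts stayed as they were.

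In all, edgeR quasi-likelihood called 6782 of 13982 tested genes at a Benjamini-Hochberg adjusted p under 0.05, 3378 higher and 3404 lower with full-length PML/RARα. Of these, 1375 had a fold change of at least 2, and a test against a fold change of 1.5 called 1307. Other large changes were rises of DBP, a clock-controlled transcription factor, by 2.64 ± 0.12, of SAPCD2 by 2.49 ± 0.08 and of the growth factor receptor gene FGFR1 by 2.27 ± 0.20, and a fall of THBS1, a secreted matrix glycoprotein gene, by 3.32 ± 0.04. The coactivator gene CREBBP rose by 1.10 ± 0.07, although camera did not call the list of nuclear receptor coregulators, with an adjusted p of 0.667. Camera adjusted p values were 0.17 for p53 target genes, 0.197 for replication-dependent histones, 0.439 for cell cycle genes, 0.442 for antigen presentation and for erythroid markers, 0.451 for lymphoid markers, 0.684 for PML nuclear body genes and 0.756 for epithelial and fibroblast markers. For heat shock genes camera gave 0.534 with a tested direction upward, against a median of -0.01 and a mean of -0.25. The panel genes ELANE, TGM2, RARB, CYP26A1 and KIT had 0 to 5 counts in each library and were not tested, and DHRS3, at 0.01 ± 0.90, did not pass.

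**Figure D2:**
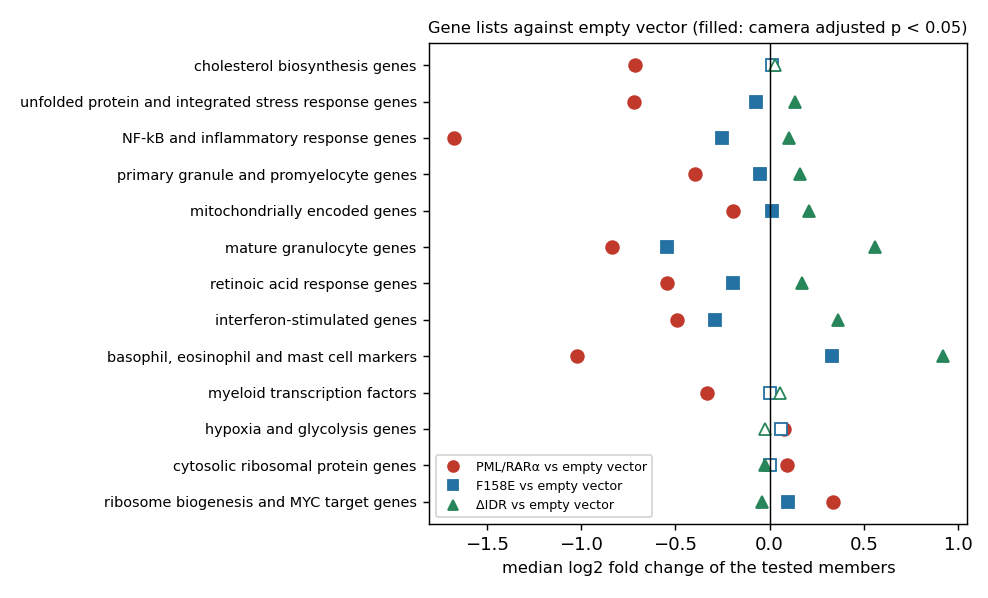
Median log2 fold change against empty vector of the tested members of 13 fixed lists of genes, for full-length PML/RARα, F158E and ΔIDR; filled points had a camera adjusted p under 0.05. The NF-kB list lay at -1.68 with full-length PML/RARα, -0.25 with F158E and 0.10 with ΔIDR.

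The comparison of F158E with full-length PML/RARα asked what this mutation takes from the fusion. CXCL8 was at 230 ± 4.31 CPM with F158E against 33.8 ± 1.62 with full-length PML/RARα, 6.78-fold higher. TNFAIP3 was at 108 ± 1.15 against 13.5 ± 0.934 CPM, and HGF, a hepatocyte growth factor gene, was 6.87-fold higher. INSIG1 stood at 438 ± 0.231 CPM and CEBPE at 65.6 ± 1.30 CPM, 3.28-fold and 2.45-fold above full-length cells. RRP1B fell by 0.75 ± 0.04.

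Cholesterol biosynthesis genes rose in 23 of 26 members and fell in 1 (23 and 1 adjusted over the list alone), with a median log2 change of 0.76 and a camera adjusted p of 5.51e-21. Unfolded protein and integrated stress response genes rose in 23 of 30 and fell in 2 (24 and 3 adjusted over the list alone), with a median of 0.69 and a camera adjusted p of 1.19e-17, and HSPA5 rose by 1.23 ± 0.02. NF-kB and inflammatory response genes rose in 26 of 35 and fell in 4 (26 and 4 adjusted over the list alone), with a median of 1.41 and a camera adjusted p of 8.08e-11. Primary granule genes rose in 17 of 23 and fell in 2 (17 and 2 adjusted over the list alone), with a median of 0.29 and a camera adjusted p of 1.29e-09, and mitochondrially encoded genes rose in 11 of 13 and fell in 1 (11 and 1 adjusted over the list alone), with a median of 0.17 and a camera adjusted p of 9.51e-14. Ribosomal protein genes fell in 38 of 70 and rose in 2 (40 and 2 adjusted over the list alone), with a median of -0.08 and a camera adjusted p of 2.80e-09. Ribosome biogenesis and MYC target genes fell in 33 of 51 and rose in 9 (34 and 9 adjusted over the list alone), with a median of -0.21 and a camera adjusted p of 1.07e-06, and MYC fell by 0.21 ± 0.03.

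Retinoic acid response genes rose in 13 of 28 and fell in 5 (13 and 5 adjusted over the list alone), with a median of 0.53 and a camera adjusted p of 6.23e-04, and CD38 rose by 1.72 ± 0.06. Myeloid transcription factors rose in 23 of 42 and fell in 7 (23 and 7 adjusted over the list alone), with a median of 0.32 and a camera adjusted p of 7.63e-04, and CEBPA, SPI1 and GFI1 rose by 0.50 ± 0.06, 0.30 ± 0.05 and 0.37 ± 0.05. Basophil, eosinophil and mast cell markers rose in 6 of 11 and fell in 0 (6 and 0 adjusted over the list alone), with a median of 1.19 and a camera adjusted p of 3.70e-06. Promyelocytic leukemia genes rose in 10 of 19 and fell in 3 (10 and 3 adjusted over the list alone), with a median of 0.26 and a camera adjusted p of 7.63e-04. Interferon-stimulated genes rose in 20 of 43 and fell in 10 (23 and 10 adjusted over the list alone), with a median of 0.40 and a camera adjusted p of 0.0320, and this call ended at an adjusted p = 0.0910 with an estimated correlation and at camera adjusted p values of 0.0542 and 0.0719 without full-length replicate 1 and 2. Hypoxia genes fell in 12 of 28 and rose in 3 (12 and 3 adjusted over the list alone), with a camera adjusted p of 0.00235, lost at an adjusted p = 0.0847 with an estimated correlation. For mature granulocyte genes, 11 of 34 rose and 8 fell (12 and 8 adjusted over the list alone), and camera did not call the list, with an adjusted p of 0.222. The complement receptor gene C5AR1 fell by 1.15 ± 0.17 and MMP9 rose by 1.46 ± 0.05.

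The edgeR quasi-likelihood test called 6126 genes for F158E against full-length PML/RARα after Benjamini-Hochberg adjustment, 3089 higher and 3037 lower. Of these, 1042 changed at least 2-fold, and a test against a fold change of 1.5 called 916. Among the named genes MACC1 fell by 2.85 ± 0.16, the membrane protein gene EMP1 fell by 2.69 ± 0.20 and FOS, an immediate-early transcription factor, fell by 2.48 ± 0.17. PML and RARA fell by 0.91 ± 0.05 and 1.25 ± 0.05, so the mutation and the amount of PML and RARA RNA changed together.

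The comparison of ΔIDR with full-length PML/RARα asked what this deletion takes from the fusion. The neutrophil defensin gene DEFA4 (ENSG00000164821.4) was at 117 ± 1.30 CPM with ΔIDR against 1.41 ± 0.310 with full-length PML/RARα, and S100A9, a calcium-binding protein of neutrophils and monocytes, at 50.5 ± 2.22 against 1.64 ± 0.0113 CPM. CXCL8 rose by 4.17 ± 0.04 on the log2 scale, to 609 ± 13.9 CPM, and IL1B by 4.64 ± 0.15, to 60.7 ± 0.579 CPM. CEBPE was at 80.6 ± 0.303 CPM and PRG2 at 504 ± 1.87 CPM, 3.01-fold and 4.14-fold above full-length cells. RRP1B was lower, at 137 ± 2.18 CPM.

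Mitochondrially encoded genes rose in 11 of 13 members and fell in 1 (11 and 1 adjusted over the list alone), with a median log2 change of 0.35 and a camera adjusted p of 2.14e-20. Unfolded protein and integrated stress response genes rose in 25 of 30 and fell in 3 (25 and 3 adjusted over the list alone), with a median of 0.92 and a camera adjusted p of 1.52e-18, and HSPA5 rose by 1.55 ± 0.02. Cholesterol biosynthesis genes rose in 21 of 26 and fell in 1 (21 and 1 adjusted over the list alone), with a median of 0.83 and a camera adjusted p of 2.63e-16. Ribosome biogenesis and MYC target genes fell in 40 of 51 and rose in 4 (42 and 4 adjusted over the list alone), with a median of -0.32 and a camera adjusted p of 1.60e-13, and MYC fell by 0.44 ± 0.03. NF-kB and inflammatory response genes rose in 27 of 35 and fell in 2 (27 and 2 adjusted over the list alone), with a median of 1.78 and a camera adjusted p of 2.16e-13. Ribosomal protein genes fell in 44 of 70 and rose in 3 (45 and 3 adjusted over the list alone), with a median of -0.13 and a camera adjusted p of 6.47e-11. Primary granule genes rose in 16 of 23 and fell in 2 (16 and 2 adjusted over the list alone), with a median of 0.48 and a camera adjusted p of 3.91e-12, and the proteinase 3 gene PRTN3 rose by 0.99 ± 0.04.

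Mature granulocyte genes rose in 26 of 34 and fell in 1 (26 and 1 adjusted over the list alone), with a median of 1.25 and a camera adjusted p of 6.38e-09, and CYBB rose by 1.16 ± 0.03. Interferon-stimulated genes rose in 29 of 43 and fell in 3 (29 and 3 adjusted over the list alone), with a median of 0.94 and a camera adjusted p of 1.70e-08, and IFIT2 rose by 3.28 ± 0.12. Basophil, eosinophil and mast cell markers rose in 9 of 11 and fell in 0 (9 and 0 adjusted over the list alone), with a median of 1.73 and a camera adjusted p of 2.62e-08, and EPX, the eosinophil peroxidase gene, rose by 2.46 ± 0.04. Retinoic acid response genes rose in 18 of 28 and fell in 4 (18 and 4 adjusted over the list alone), with a median of 0.78 and a camera adjusted p of 9.02e-08, and CD38 rose by 2.10 ± 0.06. Myeloid transcription factors rose in 22 of 42 and fell in 9 (22 and 9 adjusted over the list alone), with a camera adjusted p of 0.00764, lost at an adjusted p = 0.0573 with an estimated correlation. The factor genes CEBPB, SPI1 and CEBPA rose by 2.55 ± 0.14, 0.67 ± 0.05 and 0.46 ± 0.06. Camera calls for heat shock, monocyte and hypoxia genes, with adjusted p values of 0.00170, 0.0101 and 0.0318, were lost at adjusted p = 0.185, 0.114 and 0.185 with an estimated correlation. Heat shock genes fell in 8 of 13 members and rose in 3 (8 and 4 adjusted over the list alone), with a median of -0.12, a mean of 0.12 and a tested direction downward. Monocyte genes rose in 10 of 18 and fell in 1 (10 and 1 adjusted over the list alone), and hypoxia genes rose in 6 of 28 and fell in 14 (6 and 14 adjusted over the list alone).

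The edgeR quasi-likelihood test called 6950 genes for ΔIDR against full-length PML/RARα after Benjamini-Hochberg adjustment, 3475 higher and 3475 lower. A fold of at least 2 was reached by 1587, the same number as a test against a fold change of 1.5 called. The matrix metalloprotease gene MMP2 fell by 3.76 ± 0.19, EMP1 by 3.29 ± 0.21 and STAB1, a scavenger receptor gene high in promyelocytic leukemia, by 1.40 ± 0.16. PML and RARA rose by 1.83 ± 0.04 and 4.14 ± 0.04, so these cells carried more PML and RARA RNA than full-length cells.

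Both mutants moved many of the same genes away from full-length PML/RARα. Among 13982 genes, 2543 were higher and 2468 lower in both mutants than in full-length cells, and 37 and 54 moved in opposite directions, where independence gave 768 and 755 shared calls. Of the genes called with full-length PML/RARα against empty vector, 2551 that had risen were lower with F158E and 2670 that had fallen were higher. For ΔIDR these numbers were 2786 and 2815, and 20 and 31 genes moved further from empty vector. Because these comparisons share the full-length libraries, 20 simulations of unchanged groups were run. In these the covariance of fold changes was 0.0683, against 0.572 between the mutants. They gave 0 shared calls, but no gene changed in them and almost no call could arise, so this is no reference for the overlap. The full-length libraries were then divided, with 1 of the 2 in each comparison and the lone library assumed to vary like the other groups. In the 2 divisions 3875 and 3891 genes moved the same way in both mutants, 4015 and 4030 calls were reversed with F158E and 4428 and 4419 with ΔIDR, and the covariance between the mutants was 0.518 and 0.515.

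Along the axis from empty vector (0) to full-length PML/RARα (1), over the 6782 genes called between them, F158E libraries lay at 0.232 ± 0.00704 (SD, n = 2) and ΔIDR libraries at 0.0540 ± 0.00987. The same calculation placed a group simulated at empty vector at 0.0422, an offset that the SD does not cover. The ΔIDR value of 0.0540 therefore does not show a distance from empty vector. The simulated changes differed from the real ones, so the offset in these data is not known exactly. Genes higher in full-length cells placed F158E at 0.251 and ΔIDR at 0.0931, and genes lower in full-length cells placed them at 0.218 and 0.0259. In another setting, 522 to 532 genes with larger changes were chosen and weighted in 1 library of each group. The other library set the origin and length of the axis. F158E libraries then lay at 0.164 to 0.181 and ΔIDR libraries at -0.0320 to -0.0142, on the other side of empty vector. Without empty vector replicate 1 or 2 the ΔIDR position was 0.111 or 0.101.

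**Figure D3:**
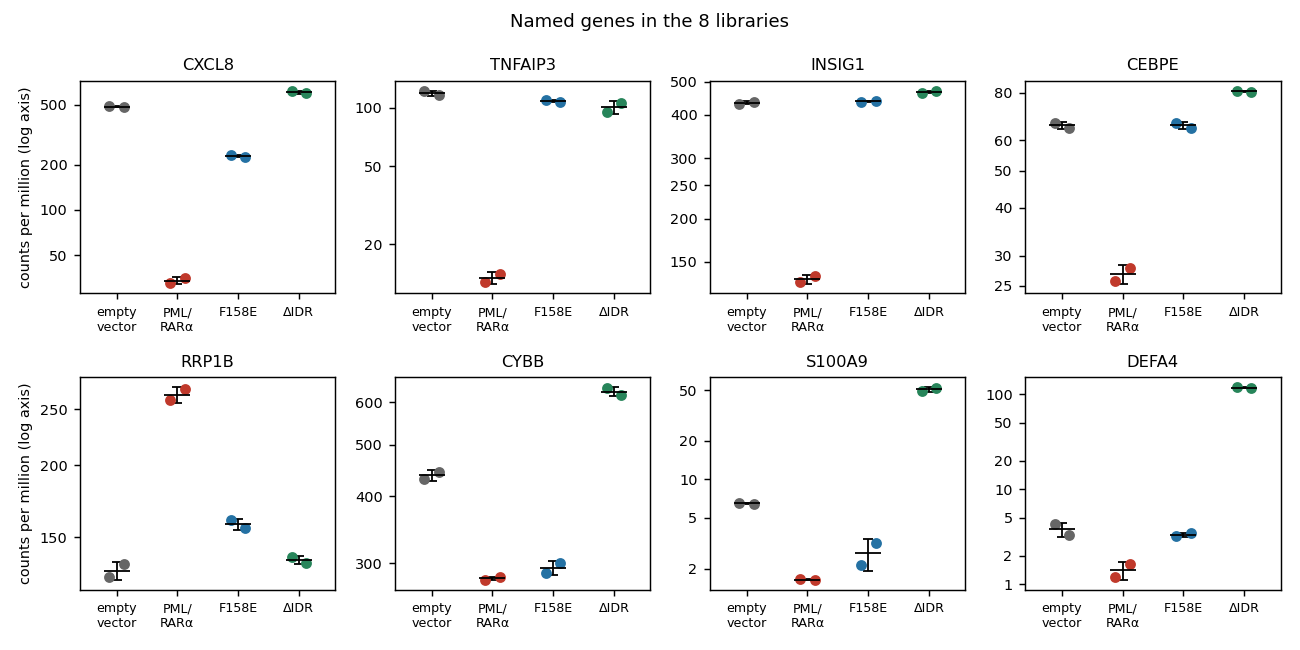
CPM on log axes for 8 named genes in the 4 groups; points are libraries, bars are the mean of 2 and error bars the SD. CXCL8 ran from 33.8 with full-length PML/RARα to 609 with ΔIDR, and DEFA4 was at 117 with ΔIDR.

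F158E cells were compared with empty vector to ask what this mutant adds to depleted cells. CXCL8 was at 230 ± 4.31 against 488 ± 2.58 CPM, a 2.13-fold fall, and NCF1 at 23.7 ± 2.06 against 56.1 ± 1.61 CPM. MMP9 fell from 350 ± 5.99 to 176 ± 5.55 CPM, THBS1 by 1.11 ± 0.03 on the log2 scale and IFI6, an interferon-induced gene, by 1.51 ± 0.20. EPX rose from 107 ± 1.25 to 210 ± 1.79 CPM and HGF from 18.2 ± 2.35 to 35.1 ± 0.433 CPM.

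Mature granulocyte genes fell in 15 of 34 members and rose in 0 (18 and 0 adjusted over the list alone), with a median log2 change of -0.54 and a camera adjusted p of 4.71e-19. Ribosome biogenesis and MYC target genes rose in 19 of 51 and fell in 0 (26 and 0 adjusted over the list alone), with a median of 0.10 and a camera adjusted p of 1.05e-16. NF-kB genes fell in 13 of 35 and rose in 1 (19 and 1 adjusted over the list alone), with a median of -0.25 and a camera adjusted p of 2.50e-14. Coagulation genes fell in 5 of 14 and rose in 0 (6 and 1 adjusted over the list alone), with a median of -0.41 and a camera adjusted p of 7.20e-10. Retinoic acid response genes fell in 9 of 28 and rose in 0 (10 and 0 adjusted over the list alone), and interferon-stimulated genes fell in 12 of 43 and rose in 0 (17 and 0 adjusted over the list alone), with camera adjusted p values of 8.69e-08 and 3.20e-07. Basophil, eosinophil and mast cell markers rose in 4 of 11 and fell in 0 (5 and 1 adjusted over the list alone), with a median of 0.33 and a camera adjusted p of 1.29e-06. Monocyte genes fell in 5 of 18 and rose in 0 (8 and 0 adjusted over the list alone), antigen presentation genes fell in 4 of 16 and rose in 0 (6 and 0 adjusted over the list alone), and promyelocytic leukemia genes rose in 6 of 19 and fell in 3 (8 and 3 adjusted over the list alone). Their camera adjusted p values were 6.34e-05, 1.55e-04 and 4.26e-04. Unfolded protein response genes fell in 5 of 30 and rose in 2 (6 and 3 adjusted over the list alone), and primary granule genes fell in 7 of 23 and rose in 1 (7 and 5 adjusted over the list alone). For these camera gave adjusted p values of 4.35e-05 and 8.29e-04. Camera calls for coregulator, mitochondrially encoded and p53 target genes, at adjusted p values of 0.00591, 0.0357 and 0.0402, were lost at adjusted p = 0.0828, 0.119 and 0.404 with an estimated correlation. Coregulator genes rose in 6 of 30 and fell in 0 (9 and 1 adjusted over the list alone), mitochondrially encoded genes rose in 1 of 13 and fell in 1 (3 and 1 adjusted over the list alone), and p53 target genes fell in 5 of 24 and rose in 0 (5 and 0 adjusted over the list alone). These calls were also lost without F158E replicate 1, at camera adjusted p values of 0.0567, 0.0521 and 0.0671, and for the latter 2 without empty vector replicate 1, at 0.0881 and 0.0836. In all camera called 15 lists. Cholesterol biosynthesis genes rose in 3 of 26 and fell in 2 (4 and 2 adjusted over the list alone), and camera did not call the list, with an adjusted p of 0.479.

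The edgeR quasi-likelihood test called 1208 genes after Benjamini-Hochberg adjustment, 555 higher and 653 lower. Of these, 108 changed at least 2-fold, 31 higher and 77 lower, and a test against a fold change of 1.5 called 23, 1 higher and 22 lower. Leaving out a library lowered the count to 646 and 688 without empty vector replicate 1 and 2 and to 765 and 772 without F158E replicate 1 and 2.

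ΔIDR cells were compared with empty vector to ask the same of the deletion mutant. DEFA4 rose from 3.79 ± 0.661 to 117 ± 1.30 CPM, a 30.9-fold rise, S100A9 from 6.48 ± 0.0612 to 50.5 ± 2.22 CPM and EPX from 107 ± 1.25 to 506 ± 5.71 CPM. SRGN rose by 0.55 ± 0.02 on the log2 scale, PRTN3 by 0.57 ± 0.03 and NCF1 by 1.69 ± 0.07. STAB1 fell by 1.60 ± 0.16, F3, the tissue factor gene, by 1.49 ± 0.10, and the lymphoid and myeloid transcription factor gene RUNX3 by 0.94 ± 0.10.

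The 13 mitochondrially encoded genes all rose (13 rose and 0 fell adjusted over the list alone), with a median log2 change of 0.21. Their camera adjusted p was 4.36e-70, and 0.00117 with an estimated correlation. The mitochondrial share of counts was 4.20% and 4.22% against 3.71% and 3.72%. Basophil, eosinophil and mast cell markers rose in 7 of 11 and fell in 1 (7 and 1 adjusted over the list alone), with a median of 0.92 and a camera adjusted p of 1.52e-13. Interferon-stimulated genes rose in 17 of 43 and fell in 0 (18 and 0 adjusted over the list alone), with a median of 0.36 and a camera adjusted p of 2.13e-11, and IFIT2 rose by 1.03 ± 0.10. Mature granulocyte genes rose in 15 of 34 and fell in 4 (19 and 5 adjusted over the list alone), with a median of 0.56 and a camera adjusted p of 2.87e-09. Primary granule genes rose in 11 of 23 and fell in 5 (12 and 6 adjusted over the list alone), with a median of 0.16 and a camera adjusted p of 7.88e-08. Heat shock genes fell in 5 of 13 and rose in 0 (6 and 0 adjusted over the list alone), with a median of -0.09. Their camera adjusted p was 5.11e-11, and 0.0395 with an estimated correlation. Coagulation genes fell in 6 of 14 and rose in 0 (7 and 0 adjusted over the list alone), with a camera adjusted p of 1.35e-05, a median of -0.23 and a mean of 0.06. Retinoic acid response genes rose in 8 of 28 and fell in 4 (12 and 4 adjusted over the list alone), with a camera adjusted p of 0.00185, lost at an adjusted p = 0.0518 with an estimated correlation. NF-kB genes rose in 8 of 35 and fell in 3 (8 and 7 adjusted over the list alone), with a median of 0.10 and a camera adjusted p of 0.0221, which was 0.0886 without empty vector replicate 1 and lost at an adjusted p = 0.0787 with an estimated correlation.

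Unfolded protein response genes rose in 10 of 30 and fell in 3 (11 and 3 adjusted over the list alone), with a camera adjusted p of 2.83e-05. Cell cycle genes fell in 13 of 54 and rose in 0 (14 and 0 adjusted over the list alone), and promyelocytic leukemia genes fell in 8 of 19 and rose in 2 (9 and 2 adjusted over the list alone). Camera adjusted p values were 1.40e-04 and 5.73e-04. Ribosomal protein genes fell in 7 of 70 and rose in 2 (8 and 3 adjusted over the list alone), with a camera adjusted p of 0.00637, which was 0.265 without empty vector replicate 1. Ribosome biogenesis genes rose in 1 of 51 and fell in 1 (0 and 0 adjusted over the list alone), with a median of -0.04 and a camera adjusted p of 0.0247. This call was lost at an adjusted p = 0.0775 with an estimated correlation and at 0.203 and 0.143 without empty vector replicate 1 and without ΔIDR replicate 2. In all camera called 14 lists. The edgeR quasi-likelihood test called 1439 genes after Benjamini-Hochberg adjustment, 702 higher and 737 lower, of which 190 changed at least 2-fold, and a test against a fold change of 1.5 called 110. Without empty vector replicate 2 the count was 883.

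The mutants were compared directly to see where they differ. DEFA4, S100A9 and NCF1 were 35.3-fold, 18.9-fold and 7.62-fold higher with ΔIDR than with F158E, CXCL8 was 2.65-fold higher and CYBB rose from 294 ± 8.64 to 629 ± 12.1 CPM. HGF was lower with ΔIDR, at 11.4 ± 0.987 against 35.1 ± 0.433 CPM, as was GAB2, a signalling adaptor gene, at 11.8 ± 1.66 against 36.6 ± 1.92 CPM. RARA CPM was 42.0-fold higher with ΔIDR, so the mutants also differed in RARA RNA.

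Mitochondrially encoded genes rose in 12 of 13 members and fell in 0 (12 and 0 adjusted over the list alone), with a camera adjusted p of 2.15e-46. Mature granulocyte genes rose in 22 of 34 and fell in 0 (24 and 0 adjusted over the list alone), with a median log2 change of 1.03 and a camera adjusted p of 8.20e-21. Interferon-stimulated genes rose in 31 of 43 and fell in 1 (35 and 1 adjusted over the list alone), with a median of 0.73 and a camera adjusted p of 2.31e-20. Ribosome biogenesis and MYC target genes fell in 35 of 51 and rose in 0 (35 and 0 adjusted over the list alone), with a median of -0.15 and a camera adjusted p of 2.37e-15. NF-kB genes rose in 15 of 35 and fell in 0 (15 and 0 adjusted over the list alone), with a median of 0.31 and a camera adjusted p of 2.13e-10. Antigen presentation genes rose in 9 of 16 and fell in 1 (9 and 1 adjusted over the list alone), with a camera adjusted p of 2.62e-04, and the class I light chain gene B2M rose by 0.15 ± 0.02. Cell cycle genes fell in 16 of 54 and rose in 1 (16 and 1 adjusted over the list alone), with a median of -0.08 and a camera adjusted p of 1.71e-05.

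Retinoic acid response genes rose in 14 of 28 and fell in 2 (14 and 2 adjusted over the list alone), and unfolded protein response genes rose in 16 of 30 and fell in 4 (18 and 4 adjusted over the list alone). The camera adjusted p values were 4.37e-10 and 1.72e-09. Primary granule genes rose in 11 of 23 and fell in 5 (11 and 7 adjusted over the list alone), and basophil, eosinophil and mast cell markers rose in 7 of 11 and fell in 1 (8 and 1 adjusted over the list alone). Camera gave them adjusted p values of 2.47e-07 and 2.09e-06. Heat shock genes fell in 8 of 13 and rose in 0 (8 and 0 adjusted over the list alone), promyelocytic leukemia genes fell in 11 of 19 and rose in 1 (12 and 1 adjusted over the list alone), and ribosomal protein genes fell in 17 of 70 and rose in 2 (19 and 3 adjusted over the list alone). These 3 lists had camera adjusted p values of 4.37e-10, 8.19e-07 and 1.23e-04, which were 0.0309, 0.0136 and 0.0153 with an estimated correlation. Monocyte genes rose in 7 of 18 and fell in 0 (7 and 0 adjusted over the list alone), and coregulator genes fell in 12 of 30 and rose in 2 (12 and 4 adjusted over the list alone). Their camera adjusted p values of 0.00155 and 0.00211 were lost at adjusted p = 0.0528 for both with an estimated correlation. In all camera called 16 lists. The edgeR quasi-likelihood test called 2592 genes after Benjamini-Hochberg adjustment, 1288 higher and 1304 lower with ΔIDR, of which 378 changed at least 2-fold.

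The share of the reads recorded in each file that fell outside annotated genes was 3.65% and 3.66% with full-length PML/RARα, 3.95% and 3.98% with empty vector, 4.29% and 4.28% with F158E and 4.27% and 4.37% with ΔIDR. The listed camera calls for which no other value is given also held with an estimated correlation, at larger adjusted p values than those printed. The larger values were not shown to come from correlation among genes. For mitochondrially encoded genes with ΔIDR against empty vector the estimate was -0.00271, below the preset 0.01. For promyelocytic leukemia genes with full-length PML/RARα against empty vector it was -0.0258, and that call was lost.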

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

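The tests of the mature granulocyte list without NCF1 and with divided empty vector libraries were chosen after the results were seen; the comparison of the mutants with each other and the shares of unassigned reads were planned. Genes and lists are given here because their values with the mutants lay in opposite directions from empty vector, each past its threshold. The direct comparison of ΔIDR with F158E gives the size of the difference; with genes chosen in this way its call adds little.

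Against empty vector, 56 genes were higher with F158E and lower with ΔIDR and 137 the reverse, where independence gave 29.3 and 32.8. In the same direction 68 genes were higher and 140 lower with both, where it gave 27.9 and 34.4. These comparisons share the empty vector libraries. The covariance of their fold changes was 0.101, where simulations of unchanged groups gave 0.0648. With 1 empty vector library in each comparison it was 0.0318 and 0.0225. Their correlation was 0.362, where the simulations gave 0.509. Real changes add variance and can lower a correlation, so the lower correlation does not show that the mutants were opposed. The 208 genes of the same and 193 of opposite direction became 86 and 98, or 94 and 117, with 1 empty vector library in each comparison, so which of them were more numerous depended on sharing. Named genes that were higher with ΔIDR and lower with F158E than with empty vector included neutrophil and granule genes, with log2 differences between the mutants of 4.24 for S100A9, 2.93 for NCF1, 2.57 for PRAM1, 2.26 for C5AR1, 1.10 for CYBB, 0.88 for PRTN3, 0.73 for SRGN and 0.55 for AZU1. Cytokine genes among them were IL1B at 2.07, CCL2 at 1.60 and CXCL8 at 1.41. The others were the retinoic acid target ASB2 at 1.44, MACC1 at 1.43, the protease gene CTSD at 1.23, the interferon-induced gene BST2 at 0.73, CD4 at 0.43 and the chaperone gene HSPA5 at 0.31. Named genes that were lower with ΔIDR and higher with F158E were FGFR1 at -1.67, HGF at -1.61, IGFBP2 at -0.82, WT1 at -0.74, HDC at -0.50, HK2 at -0.28 and MYC at -0.23. Against empty vector, S100A9 changed by 2.96 ± 0.16 with ΔIDR and -1.28 ± 0.20 with F158E.

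Of the lists, those with a higher median in ΔIDR than in F158E were mature granulocyte genes at 1.03, interferon-stimulated genes at 0.73, retinoic acid response genes at 0.39, NF-kB genes at 0.31, unfolded protein response genes at 0.21 and primary granule genes at 0.13. Genes high in promyelocytic leukemia, at -0.20, and ribosome biogenesis genes, at -0.15, had lower medians in ΔIDR. Against empty vector, the ΔIDR calls for retinoic acid, NF-kB and ribosome biogenesis genes were lost at camera adjusted p = 0.0518, 0.0787 and 0.0775 with an estimated correlation. Of the 51 ribosome biogenesis genes 1 rose and 1 fell with ΔIDR (0 and 0 adjusted over the list alone), with a median of -0.04, and the call was lost at camera adjusted p = 0.203 and 0.143 without empty vector replicate 1 and without ΔIDR replicate 2. The NF-kB call was lost at camera adjusted p = 0.0886 without empty vector replicate 1.

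The opposite movement of mature granulocyte genes is a pattern to follow up. Without NCF1, which has near-identical copies and is 1 of the 22 members that rose, the camera adjusted p was 6.93e-18 between the mutants, within a range of 1.42e-25 to 0.00323 over the alternatives for this list. No technical explanation was tested for this pattern. A different effect of the mutant proteins remains open as a hypothesis, as does the amount of PML and RARA RNA, which differed between the mutants in the same libraries. The labels do not say whether cells of different groups were handled together, so a difference in culture state is open too.

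Among the reads outside the gene counts, the share with no gene was above both empty vector libraries with F158E, at 4.29%, and with ΔIDR, at 4.32%. The share of reads that fitted more than 1 gene was above both empty vector libraries with full-length PML/RARα, at 3.46%. No test was made of these shares.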

How the results depend on the processing

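The tests against a fold change of 1.5, on thinned counts, without NCF1 and with divided full-length or empty vector libraries were chosen after the data were seen. In all, 553 results were recomputed, which gave 5040 alternative values. Of the values for named genes, 3962 stayed on the same side of the threshold, and 43 lost it, 40 of them when a library was left out and 3 with DESeq2. Direction was compared only where the main or the alternative value passed. Named genes were not followed under the count filters, thinned counts, GC correction, the test against 1.5, the 4 libraries alone or protein-coding genes alone. For the lists that camera called, 775 values kept direction and threshold and 31 lost the threshold, 19 with an estimated correlation, 11 when a library was left out and 1 with fry. Within these limits no named gene or list changed direction, and in no setting did a called gene that stayed called change sign. With DESeq2 size factors or library totals the median log2 change of all genes stayed within 0.0235 of 0. With GC correction 39.5% of 1541 ΔIDR calls against empty vector and 44.3% of 7071 against full-length PML/RARα were higher.

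A fold change of at least 2 left 1375, 1042, 1587, 108, 190 and 378 genes, in the order of the report, because it drops small changes by construction, and a test against 1.5 left 1307, 916, 1587, 23, 110 and 215. The same fold limit left 751 genes shared by the mutants against full-length PML/RARα, and 763 and 986 reversed by F158E and ΔIDR, and 10 genes of the same and 12 of opposite direction against empty vector in the mutants. Those 2 counts, 208 and 193 at first, were 118 to 185 and 90 to 153 when a library was left out, and 86 and 98, or 94 and 117, with 1 empty vector library in each comparison. With fry, which asks another question, 20 and 25 lists passed for F158E and ΔIDR against full-length PML/RARα. The replicate block gave 6763, 6098, 6923, 1225, 1442 and 2615 genes, and DESeq2 gave 6191, 5423, 6394, 832, 1138 and 2061.

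The F158E position was 0.246 over genes with a fold of at least 2, and 0.172, 0.177, 0.169 and 0.171 where genes were chosen in 1 library of each group. The ΔIDR position reversed sign to -0.0148, -0.0180, -0.0172 and -0.0298 in the latter setting. There the libraries that chose the genes also weighted them, and the other libraries set the origin and length of the axis. That setting used only 522 to 532 genes, with a fold of at least 2 and a mean of at least 3 log2 CPM. The reversal therefore cannot be credited to the division of libraries alone. Leaving out 1 library, with the lone one assumed to vary like the other groups, gave positions of 0.213 to 0.277 for F158E and 0.0407 to 0.111 for ΔIDR. It left 646 to 772 genes for F158E and 883 to 1136 for ΔIDR against empty vector, 5707 to 5793 for full-length PML/RARα against empty vector, 5059 to 5214 and 6006 to 6167 for the mutants against full-length PML/RARα, and 1881 to 2064 between the mutants. On counts thinned to 1 part in 3, the 6 comparisons gave 5572, 5001, 5782, 817, 1050 and 1947 calls, each fewer than at full depth. Beyond these constructions, the cause was not tested.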

Other observations

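The tests of transgene RNA, of mixed RNA, of the spread of list positions, of thinned counts and of GC content were chosen after the results were seen, and those of library scaling and of chromosomes before. DEFA3, S100A8 and CXCR2 were chosen after their values were seen.

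The genes picked in this way were compared between ΔIDR and empty vector. DEFA3, a neutrophil defensin gene, was at 10.2 CPM with ΔIDR and 0.0264 CPM with empty vector, where its counts were 0 and 1, and it too has near-identical copies. S100A8, the partner of S100A9 in calprotectin, was at 11.3 CPM against 1.31 CPM, a log2 rise of 3.11 ± 0.35 with an edgeR adjusted p of 1.76e-11. The chemokine receptor gene CXCR2 rose by 0.63 ± 0.21 with an edgeR adjusted p of 0.0352, with n = 2 libraries in each group. They stand for no set: 4 mature granulocyte genes fell with ΔIDR, and MMP9 among them went from 350 ± 5.99 to 169 ± 0.386 CPM.

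Gene groups sat at different places along the axis from empty vector (0) to full-length PML/RARα (1), measured on the linear scale over called members. For F158E the median position was 0.588 for mature granulocyte genes, 0.343 for NF-kB genes, 0.127 for unfolded protein response genes and -4.02e-04 for cholesterol genes. Permuting members among all lists gave p values for the spread of all list medians of 0.0142 over called members and 0.0219 over those with a fold of at least 2, with no allowance for unequal noise. For ΔIDR the median position was 0.186 for promyelocytic leukemia genes (quartiles -0.364 to 0.518) and 0.182 for cell cycle genes (0.0191 to 0.312). It was 0.0213 for cholesterol genes (-0.196 to 0.181) and 0.0191 for mature granulocyte genes (-2.61 to 0.452). Lower medians were -0.439 for interferon-stimulated genes (-0.888 to -0.0495) and -0.459 for mitochondrially encoded genes (-1.14 to -0.382). The lowest of these lists were primary granule genes at -0.549 (-0.979 to 0.215) and the 7 basophil, eosinophil and mast cell markers at -1.61 (-15.3 to -0.230). The quartiles of the promyelocytic leukemia, cholesterol, mature granulocyte and primary granule genes thus lay on both sides of empty vector.

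Replicates differed by 3.77 times the counting variance at most, in the F158E libraries and the class of genes with the most counts. In 8 of 8 libraries more genes had a count of 4 than a count of 3. From the class with the fewest counts to that with the most, the ratio rose by what a CV of 0.287% to 1.01% in the groups would add, and a CV of 5% would have given 12.1 to 13.9. The excess of counts of 4 may mean that reads were counted more than once, which was not tested and would change what counting variance, SE and p-values mean. On counts thinned to 1 part in 3, full-length PML/RARα against empty vector gave 5572 calls.

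F158E libraries lay near empty vector. A fixed share of full-length RNA mixed into libraries like empty vector would move genes only toward full-length cells, but of the F158E calls against empty vector that full-length cells shared, 933 had the same direction and 78 the opposite one, against 60.4 errors allowed among all the F158E calls. The test thus went against mixing as the whole source, but only by a little. The 60.4 holds only if the adjusted p values are right, which technical replicates would upset. Of the 78 genes, 14 changed at least 2-fold between full-length cells and empty vector. Mixing as the whole source is therefore not settled, and mixing behind the 933 is open. Little F158E transgene RNA may account for the pattern, as a hypothesis, since RARA above empty vector was 0.171 of that in full-length cells, if that RNA stands for the transgene. Loss of function through the mutation remains open and untested, because the design changed the protein and its RNA amount together.

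Full-length libraries stood apart from the other 3 groups. GC content and length explained a share of 0.00872 of the variance of their fold changes against empty vector. The autosome farthest from 0 had a median log2 change of -0.0827. These values argue against GC content, length and gain or loss of whole autosomes as the main source. Library totals in place of TMM gave 6835 calls, 6611 of them among the 6782 called with TMM. Because TMM factors were 0.989 to 1.01, these scalings were nearly alike, so the test could not decide about scaling. An effect of the fusion protein is a candidate explanation that these tests leave standing as a hypothesis. A difference in culture, infection or library preparation that fell on both full-length libraries is likewise open, as the labels give no batch.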
